A study of Mus musculus with 12 samples.

How the data were processed

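RNA was measured by sequencing in 12 libraries from mice whose Foxp3 locus also encodes GFP (FOXP3-IRES-GFP). Of these, 6 libraries came from naive CD4+ conventional T cells (Tcon) and 6 from CD4+CD25+FOXP3+ regulatory T cells (Treg). Per the labels' protocols, mice received vehicle or 25 mg/kg of SAH-FOXP3(229-259)C, a stapled alpha-helical peptide, by a daily intraperitoneal injection for 2 days. Vehicle libraries carry DMSO in their titles. RNA was extracted with Trizol and a column kit, and libraries were made with a stranded Illumina mRNA kit, per the labels' protocols. Each cell type has 1 vehicle and 2 SAH libraries from lymph node and 1 vehicle and 2 SAH libraries from spleen. Library numbers 01 to 06 in the titles are each shared by 1 Treg and 1 Tcon library: 01 is lymph node vehicle, 02 and 03 lymph node SAH, 04 spleen vehicle, 05 and 06 spleen SAH. The labels used here do not say whether these libraries came from separate mice, or whether lymph node and spleen libraries share a mouse, so the p-values measure only the spread between these samples, which may be technical.

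The processing notes of the submitters name TopHat, Bowtie and edgeR and the mouse genome build mm10, without versions; the annotation and the counting program are not given in the sources used here. The authors deposited 1 table for each cell type, with a normalized signal for every gene and library that the file headers call CPM. The column totals differed between libraries, from 971928 to 1.02143e+06, so each library had also been scaled by a factor of its own. The deposited log2 values are the authors' fold change of SAH against vehicle and a mean log2 CPM per gene, per the file headers. The deposited scores are a likelihood ratio statistic and a call of up, down or neither for each gene, per the file headers. The deposited p-values come with a false discovery rate that equals the Benjamini-Hochberg adjustment over all genes of the table to within 1.77e-05. The authors' comparison is used here only where it is named.

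The Treg table lists 10405 gene symbols and the table of Tcon lists 9886, of which 9784 are in both. Every listed gene reached a value of 1 in at least 3 libraries of its table, so genes below that level were not analysed here. Low values in each library were whole multiples of the worth of 1 read, and 100% of values came out within 0.1 of a whole read. The rebuilt depth in the listed genes was 36442420 to 48888678 reads per library, at which 1 read is worth at most 0.0267 CPM. Some symbols stand for 1 gene under both an old and a new name: 284 Treg and 272 Tcon symbols share all of their values with another symbol. They were kept, and the tests were repeated with 1 symbol for each gene. Date-like symbols, 13 in the Treg table and 12 in the Tcon table, could not be matched to genes and were tested but never named. In all, 95.9% of Treg symbols matched the GENCODE annotation of mm10, from which coordinates were taken. Libraries of an organ and treatment differed by more than counting noise (chi-square per degree of freedom 9.15 to 20.9), so none holds the same reads as another, which does not show that they came from separate mice.

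Values were analysed as log2(CPM + 1) with R 4.3.3 and limma 3.58.1 (linear model and empirical Bayes with an intensity trend, two-sided). Genes needed at least 1 CPM in at least 2 libraries, which removed 0 genes. Within each cell type, organ and treatment were terms of 1 model with 3 residual degrees of freedom, which gave the SAH effect and the organ difference. As each organ has 1 vehicle library, leaving out 01 or 04 leaves the SAH effect to spleen or lymph node alone. The difference of the SAH effect between organs was an interaction term with 2 residual degrees of freedom, both from pairs of SAH libraries, and the difference between cell types was tested in 1 model of all 12 libraries. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over all genes of a comparison, and a gene was called below 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of genes with few reads, and intervals are 95% intervals of the model. Levels are CPM of single vehicle libraries and mean ± SD of 2 SAH libraries. Levels were never tested between the Treg and Tcon tables, which had been normalized separately.

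A total of 26 gene lists, on Treg biology, T cell function, stress, metabolism and markers of other cells, was fixed together with the tests and the rule for naming genes before the data were examined. The 22 lists with at least 5 measured genes were tested with camera of limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. No list call held with an estimated correlation in any comparison. That setting of camera also rests on the residual degrees of freedom, 3 within a cell type. With so few, a call can be lost even at a low estimated correlation, so the loss does not show that correlation made the call. Fits with a library left out were run at the preset correlation only, and not for list differences between cell types. Lists can share genes. Genes are named by rule: the 10 largest rises and 10 largest falls among called genes that moved the same way in every organ or treatment, a set of Treg and activation genes in every comparison, the 4 genes with the smallest p of each list that passed, and the 5 smallest p in each direction for interactions. Some genes that these rules pick are not reported here. Other genes named were chosen after their values were seen.

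Numbers shared between a Treg and a Tcon library were checked as a pairing by correlating the libraries' deviations from the fitted means across genes. The correlation was 0.286 to 0.537 for 6 of 6 numbers, each higher than with any other number. The values of 01 and 04 are not independent, because the model mirrors them. With 3 residual degrees of freedom the numbers hold few separate differences, whose directions could match by chance, so the pairing is not established. The pairing used here is taken from the titles and these correlations. Pairing enters the comparison between cell types only.

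The rebuilding of reads, the gene tests and the list test at the preset correlation were run on simulated reads with the real means and library sizes. All genes of a table had the same dispersion, and libraries were independent, without organ or library effects other than the simulated change. Recovery in the real data may therefore be lower. Of genes changed 1.5-fold, 86% were recovered in the Treg SAH comparison and 91% in the Tcon one, and 100% in both at 2-fold. For the organ differences, 93% (Treg) and 90% (Tcon) were recovered at 1.5-fold. For the interaction with organ, the shares were 7% and 16% at 1.5-fold and 63% in both cell types at 2-fold. For the difference between cell types they were 45% at 1.5-fold and 97% at 2-fold. Unchanged genes made up 3 of 189 calls in Treg and 13 of 204 in Tcon for SAH, and 14 of 206 and 11 of 201 for organ. For the interaction they made up 2 of 72 and 2 of 81, and between cell types 4 of 146. Alternatives planned were another pseudocount (0.25), no filter, median-of-ratios rescaling, no organ term, each organ alone, SAH libraries alone, an estimated correlation, the pairing, leaving out each library in turn, and edgeR on rebuilt reads, which was not run. Alternatives chosen after seeing the data were limma voom on rebuilt reads, 1 prior variance for all genes, and 1 symbol for each gene.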

Results

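The series title concerns the inhibition of FOXP3, the transcription factor that defines Treg, by stapled peptides, and the libraries let the RNA of Treg and Tcon be compared after SAH or vehicle in lymph node and spleen. Foxp3 (chromosome X, 7573644 to 7595245 in mm10) was measured at 690 ± 27.2 CPM in Treg and 22.3 ± 1.85 CPM in Tcon (SD, n = 6 each), a ratio of 31.0. Il2ra, the gene of CD25, was at 667 ± 111 CPM in Treg and 5.19 ± 1.39 CPM in Tcon (SD, n = 6 each), a ratio of 128. The T cell genes Cd4 and Cd3e were abundant in both, at 719 ± 20.6 and 403 ± 12.5 CPM in Treg and 992 ± 28.0 and 336 ± 14.2 CPM in Tcon (SD, n = 6 each). These levels come from tables normalized separately and were not tested against each other. Correlations between libraries of a cell type were at least 0.985.

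**Figure D1:**
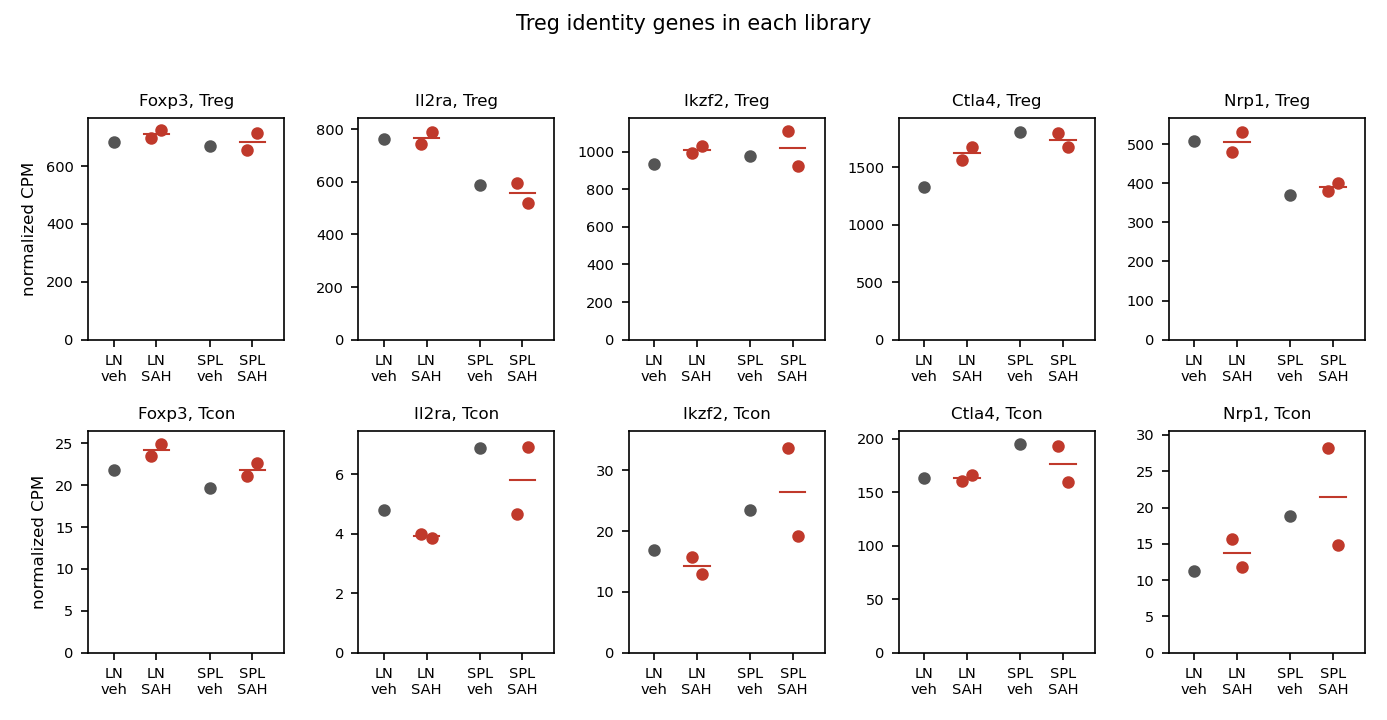
Levels of 5 Treg identity genes in each library (y axis, normalized CPM; upper panels Treg, lower panels Tcon), with Foxp3 between 655 and 726 CPM in all 6 Treg libraries. LN is lymph node, SPL spleen and veh vehicle; grey points are the single vehicle libraries, red points the SAH libraries and red bars their means of 2.

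In Treg, SAH was followed by higher RNA of the chaperone genes Hspa1a, Hspa1b, Hspa1l, Hsph1 and Dnajb1 and lower RNA of the fatty acid import pair Cpt1a and Slc25a20. Hspa1a, an inducible HSP70 chaperone, rose 3.42-fold (95% interval 3.06 to 3.83, adjusted p = 8.01e-09), from 21.5 CPM in lymph node vehicle to 71.0 ± 10.8 CPM in SAH and from 62.1 to 231 ± 3.30 CPM in spleen (SD, n = 2 each). The neighbouring genes Hspa1b and Hspa1l rose 3.35-fold and 3.02-fold, and the chaperones Hsph1 (HSP110 family) and Dnajb1 (HSP40 family) rose 1.46-fold and 1.31-fold. Cpt1a, which loads long-chain fatty acids onto carnitine at the mitochondrion, was 1.59-fold lower (log2 change -0.67, 95% interval -0.77 to -0.56, adjusted p = 4.75e-06). It went from 193 to 119 ± 3.90 CPM in lymph node and from 200 to 128 ± 1.08 CPM in spleen (SD, n = 2 each). Slc25a20, the mitochondrial carnitine carrier, was 1.29-fold lower (adjusted p = 0.041), and the peptide transporter gene Slc15a2 was 1.69-fold lower (adjusted p = 5.93e-06).

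Of 10405 genes, 21 were called. With SAH 14 were higher and 7 lower, 9 of them by more than 1.5-fold and 3 by more than 2-fold, while 733 genes had an unadjusted p below 0.05. All 21 moved the same way in both organs and in 4 of 4 SAH libraries, as 25.2% of all genes did and 22.2% would by chance. The call itself favours genes whose libraries agree, so this is no separate support for the 21. The 22.2% takes the organs as independent and would be too low if lymph node and spleen libraries shared mice. Itgae, which encodes the integrin chain CD103, rose 1.46-fold (95% interval 1.33 to 1.61, adjusted p = 0.000918), from 141 to 213 and 228 CPM in lymph node and from 52.5 to 72.7 ± 6.51 CPM (SD, n = 2) in spleen. Cfap74 rose 1.88-fold at a level under 6 CPM, and S100a6, S100a4, Anxa2 and Lgals1, calcium-binding or lectin genes, rose between 1.25-fold and 1.34-fold. Lower genes were Selp (log2 change -0.70), Cdk5rap1 (-0.67), Camk2n1 (-0.62) and Art2b (-0.41). Without lymph node vehicle library 01 the count was 7, without lymph node SAH libraries 02 or 03 it was 8 or 9, and without spleen SAH libraries 05 or 06 it was 56 or 95. Of the 18 called genes named by rule, Hspa1a, Hspa1b, Hspa1l, Cpt1a and Slc15a2 kept their call in 6 of 6 left-out fits. Itgae lost it without library 01 (log2 change 0.46, adjusted p = 0.114) and Hsph1 without library 04 (0.45, adjusted p = 0.234). Dnajb1 lost it without 02, 03 or 04 (0.45, 0.38 and 0.24) and Slc25a20 without 01, 02, 03 or 04 (-0.42, -0.39, -0.36 and -0.31). Each of the others lost it in 2 to 4 fits, always without a vehicle library or a lymph node SAH library.

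Foxp3 itself was at 682 CPM in lymph node vehicle and 711 ± 20.4 CPM in SAH, and at 669 and 685 ± 42.3 CPM in spleen (SD, n = 2 each), a log2 change of 0.05 (95% interval -0.07 to 0.17, adjusted p = 0.955). Il2ra (fold 0.974, 95% interval 0.887 to 1.07), Ctla4 (1.08, 0.962 to 1.22), Ikzf2 (1.06, 0.955 to 1.18), Tnfrsf18 (0.973, 0.882 to 1.07) and Nrp1 (1.02, 0.942 to 1.11) did not pass. The cytokine genes Il10 (fold 0.84, adjusted p = 0.705) and Ifng (log2 change 0.04, adjusted p = 0.978), the activation gene Cd69 (fold 1.1, adjusted p = 0.587) and the proliferation gene Mki67 (1.18, adjusted p = 0.347) did not pass either.

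Of 34 genes of the Treg signature, 1 rose (Itgae), 0 fell and 33 did not pass (3 rose adjusted over the list alone), and the list did not pass (camera adjusted p = 0.601), although it passed upwards without spleen vehicle library 04 (adjusted p = 0.000324) or spleen SAH library 06 (adjusted p = 0.0206). Of 15 genes known to be repressed by FOXP3, 0 were called (0 adjusted over the list alone; adjusted p = 0.825), with Il7r at a log2 change of 0.21 and Bach2 at -0.17. Of 28 genes of FOXP3 partners, 0 were called (0 adjusted over the list alone; adjusted p = 0.784). The immediate-early (adjusted p = 0.27), interferon response (adjusted p = 0.0794) and ribosomal protein lists (adjusted p = 0.903) did not pass either. Adjusted over the list alone, 5 of 30 immediate-early genes rose and 0 fell, and 0 genes of the other 2 lists passed. Fits with a library left out used the preset correlation only, at which list calls come more easily. The interferon list passed upwards without lymph node SAH library 03 (adjusted p = 0.000956), spleen vehicle library 04 (adjusted p = 0.000399) or spleen SAH library 06 (adjusted p = 6.57e-06).

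Among gene groups in Treg, 9 of 22 lists passed, all upwards (4 without lymph node vehicle library 01). Of 22 heat shock and integrated stress genes, 4 rose, 0 fell and 18 did not pass (9 rose adjusted over the list alone), with a median log2 change of 0.14 (adjusted p = 4.38e-10); adjusted p = 0.113 with an estimated correlation. Of 20 cholesterol synthesis genes, 0 passed alone, 5 rose adjusted over the list alone and 19 had a positive change, with Idi1 at 0.32 and Insig1 at 0.23 (adjusted p = 3.72e-08); adjusted p = 0.492 with an estimated correlation. These 2 lists passed in 6 of 6 left-out fits. Of 25 effector Treg genes, 3 rose (Itgae, S100a4, Lgals1), 0 fell and 22 did not pass (6 rose adjusted over the list alone; adjusted p = 0.000544), with Gzmb at 0.59 and Lgals3 at 0.76 not passing; adjusted p = 0.492 with an estimated correlation. The effector Treg call was lost without lymph node vehicle library 01, where the SAH effect rests on spleen alone.

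In each of the other lists that passed in Treg, at most 1 gene was called. Of 39 cell cycle genes, 0 passed alone (0 adjusted over the list alone) and 34 had a positive change, such as Mki67 at 0.24, Rrm2 at 0.29 and Ube2c at 0.39 (adjusted p = 1.33e-06); adjusted p = 0.492 with an estimated correlation. Without lymph node vehicle library 01 the cell cycle list stood at adjusted p = 0.266 at the preset correlation. All 13 mitochondrially encoded genes had a positive change and 0 passed (0 adjusted over the list alone), with mt-Co2 at 0.13 and mt-Nd3 at 0.12 (adjusted p = 0.000544); adjusted p = 0.641 with an estimated correlation. Without spleen vehicle library 04 or spleen SAH library 05 the mitochondrial list stood at adjusted p = 0.662 and adjusted p = 0.0663 at the preset correlation. Of 17 glycolysis genes, 0 passed (1 rose adjusted over the list alone), with Slc2a1 at 0.21 and Pfkp at 0.14 (adjusted p = 0.00444). Of 24 trafficking receptors only Itgae rose (3 rose adjusted over the list alone) and 7 had a negative change, with Cxcr4 at 0.27 and Itga4 at -0.15 not passing (adjusted p = 0.0157). Of 17 STAT5 and cytokine feedback genes 0 passed (1 rose adjusted over the list alone) and 6 had a negative change, with Gzmb at 0.59, Socs3 at 0.16 and Pim2 at 0.20 (adjusted p = 0.0332). With an estimated correlation these 3 lists stood at adjusted p = 0.492, adjusted p = 0.492 and adjusted p = 0.573. Without lymph node vehicle library 01 they stood at adjusted p = 0.162, adjusted p = 0.642 and adjusted p = 0.478. Without lymph node SAH library 03 trafficking stood at adjusted p = 0.0531 and STAT5 at adjusted p = 0.0643, and without spleen SAH library 05 STAT5 stood at adjusted p = 0.157. The list of myeloid and dendritic markers passed upwards as well (10 genes, 0 passing, 0 adjusted over the list alone; adjusted p = 0.0103, and adjusted p = 0.492 with an estimated correlation). At the preset correlation this list stood at adjusted p = 0.878 without spleen vehicle library 04 and adjusted p = 0.0974 without spleen SAH library 06. The B cell marker list (10 genes, 0 called, 0 adjusted over the list alone; adjusted p = 0.131) passed upwards without spleen vehicle library 04 (adjusted p = 0.000886) or spleen SAH library 05 (adjusted p = 1.14e-06). The apoptosis and p53 list (25 genes, 0 called, 0 adjusted over the list alone; adjusted p = 0.0569) passed upwards without spleen vehicle library 04 (adjusted p = 0.00645) or spleen SAH library 06 (adjusted p = 0.0164). Lyz2 was at 21.6 CPM in vehicle and 45.2 ± 9.92 CPM in SAH in spleen, and at 1.29 and 1.11 ± 0.302 CPM in lymph node (SD, n = 2 each).

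In Tcon, Hspa1a, Hspa1b and Hspa1l had the largest rises among the called genes. Hspa1a rose 5.27-fold (95% interval 3.7 to 7.5, adjusted p = 0.0017), from 29.3 to 126 ± 55.7 CPM in lymph node and from 40.2 to 287 ± 27.6 CPM in spleen (SD, n = 2 each), with Hspa1b at 5.17-fold and Hspa1l at 3.76-fold. Vegfa, an angiogenic growth factor gene, rose 2.07-fold (95% interval 1.81 to 2.36, adjusted p = 0.000789). Fosl2, of the AP-1 family, rose 1.64-fold (1.5 to 1.79, adjusted p = 0.000789) from 359 to 579 ± 38.2 CPM in lymph node and from 356 to 594 ± 20.4 CPM in spleen (SD, n = 2 each). Gimap7, a GTPase gene of the lymphocyte GIMAP family, was 1.77-fold lower (log2 change -0.82, 95% interval -0.97 to -0.68, adjusted p = 0.000789). It stood at 54.5 against 30.5 ± 2.54 CPM in lymph node and 85.9 against 48.0 ± 2.06 CPM in spleen (SD, n = 2 each). Cpt1a was 1.6-fold lower (adjusted p = 0.000951) and Slc25a20 1.36-fold lower (adjusted p = 0.0192).

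Of 9886 genes in Tcon, 103 were called. With SAH 87 were higher and 16 lower, 24 by more than 1.5-fold and 5 by more than 2-fold, with 1391 genes at an unadjusted p below 0.05. All 103 moved the same way in both organs and in 4 of 4 SAH libraries, which the call itself favours. Of all genes 33.3% did, against 22.2% by chance if the organs are independent. With shared mice that chance share would be higher. Further rises were Drc1 (2.14-fold, at under 7 CPM), Hsph1 (1.64-fold), Klf4 (1.6-fold) and Csrnp2 (1.59-fold). Further falls, as log2 changes, were Slc15a2 (-0.70), Art2b (-0.68), Cdk5rap1 (-0.66), Zfp617 (-0.49), Adk (-0.43) and Casp9 (-0.41). Foxp3 (fold 1.1, 95% interval 0.995 to 1.23), Il2ra (0.848, 0.691 to 1.04), Ctla4 (0.949, 0.843 to 1.07), Ifng (1.02, 0.839 to 1.24) and Cd69 (0.923, 0.839 to 1.02) did not pass. The Treg signature (28 genes, 0 called, 1 adjusted over the list alone) stood at adjusted p = 0.484, and at adjusted p = 0.0163 without spleen SAH library 06. The count was 30 without lymph node vehicle library 01, 226 and 11 without lymph node SAH libraries 02 and 03, 15 without spleen vehicle library 04, and 66 and 32 without spleen SAH libraries 05 and 06. Of the 28 called genes named by rule, 7 kept their call in all 6 left-out fits: Hspa1a, Hspa1b, Vegfa, Fosl2, Gimap7, Cpt1a and Nr4a2. Hspa1l, Hsph1 and Dnajb1 lost it without libraries 03 or 04. There Hspa1l was at log2 changes of 1.82 and 1.44 (1.91 with all libraries), Hsph1 at 0.67 and 0.58 (0.71) and Dnajb1 at 0.59 and 0.50 (0.61). Slc15a2 lost it without 01 or 03 (log2 change -0.50 and -0.68, against -0.70). Slc25a20 lost it without 01, 03, 04 or 06 (log2 change -0.54, -0.44, -0.34 and -0.42). The remaining named genes lost it in 1 to 5 fits, without library 01, 03, 04, 05 or 06.

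Of 22 lists in Tcon, 6 passed, all upwards, and each passed in 6 of 6 left-out fits. Without lymph node vehicle library 01 the count was 13, of which 6 were downwards: CD8 and natural killer markers (adjusted p = 0.000102), B cell markers (adjusted p = 3.03e-05), effector Treg genes (adjusted p = 5.65e-05), trafficking receptors (adjusted p = 0.000833), helper lineage genes (adjusted p = 0.0316) and interferon response (adjusted p = 0.0455). These fits used the preset correlation only, and without library 01 the SAH effect rests on spleen alone. With all libraries the CD8 and natural killer list (10 genes, 0 called, 0 adjusted over the list alone, median -0.20) stood at adjusted p = 0.0679. It also passed downwards without lymph node SAH library 02 (adjusted p = 0.00516) or spleen SAH library 05 (adjusted p = 0.0394), as did interferon response (adjusted p = 0.0105 and adjusted p = 0.0394). Helper lineage genes passed downwards without library 05 too (adjusted p = 0.0253), and effector Treg genes upwards without spleen vehicle library 04 (adjusted p = 0.0174). Mitochondrially encoded genes passed upwards without library 01 (adjusted p = 0.0447) or 02 (adjusted p = 0.0438). Of 22 heat shock and integrated stress genes, 9 rose, 0 fell and 13 did not pass (16 rose adjusted over the list alone), among them Dnajb1 (log2 change 0.61), Hsp90aa1 (0.35), Ddit3 (0.42) and Hspa8 (0.37) (adjusted p = 1.5e-15, and adjusted p = 0.311 with an estimated correlation). Of 29 immediate-early and T cell receptor response genes, 6 rose, 0 fell and 23 did not pass (13 rose adjusted over the list alone), including Nr4a3 (0.66), Nr4a2 (0.55) and Ppp1r15a (0.43) (adjusted p = 4.07e-08, and adjusted p = 0.434 with an estimated correlation). Of 51 ribosomal protein genes, 1 rose (Rpl38 at 0.32), 0 fell and 50 did not pass, but 50 had a positive change and 22 rose adjusted over the list alone (median 0.17; adjusted p = 1.5e-15, and adjusted p = 0.538 with an estimated correlation). Of 20 cholesterol synthesis genes, 2 rose (Insig1 at 0.47 among them), 0 fell and 18 did not pass (12 rose adjusted over the list alone; adjusted p = 5.98e-10, and adjusted p = 0.405 with an estimated correlation). Glycolysis had 1 rise among 17 genes (Slc2a1 at 0.34; 2 rose adjusted over the list alone; adjusted p = 1.78e-05, and adjusted p = 0.405 with an estimated correlation). STAT5 and cytokine feedback genes had 1 among 16 (Socs3 at 0.64; 3 rose adjusted over the list alone; adjusted p = 0.000857, and adjusted p = 0.319 with an estimated correlation).

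**Figure D2:**
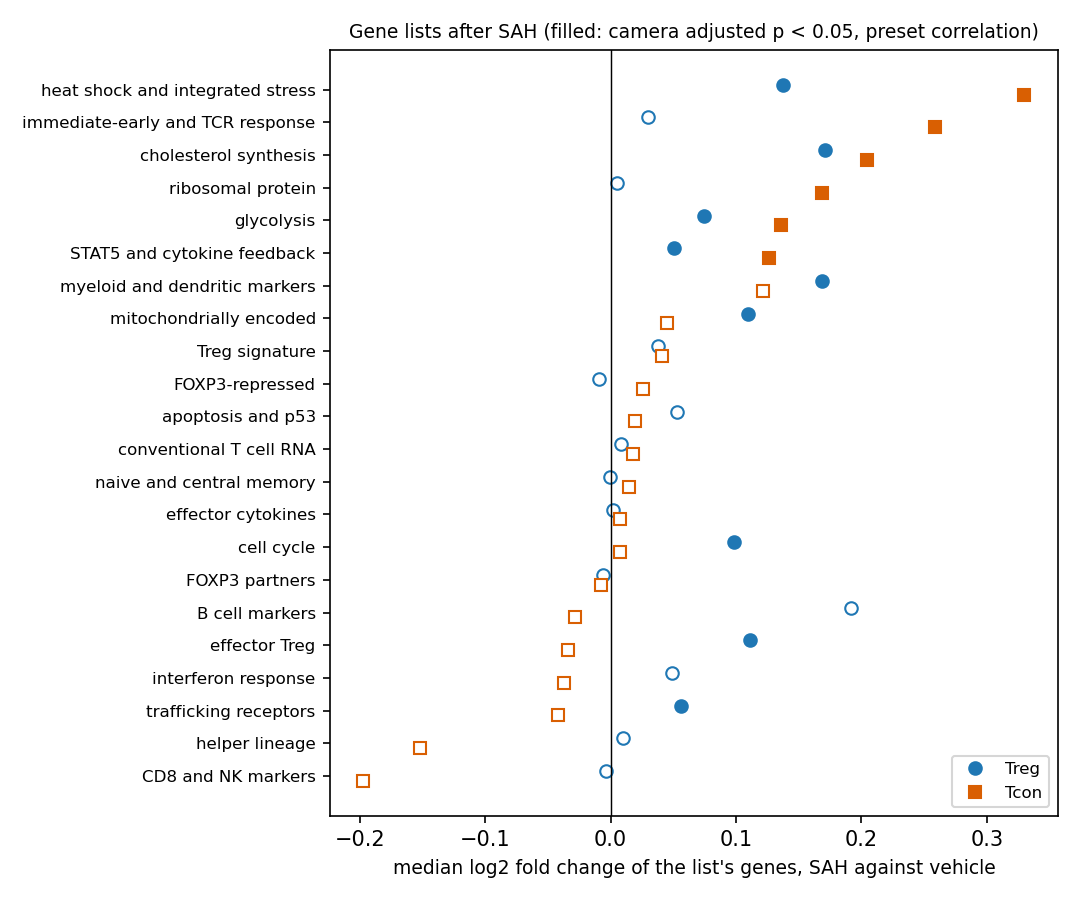
Median log2 fold change of each tested gene list, SAH against vehicle (x axis), for Treg (circles) and Tcon (squares). Filled symbols passed camera at the preset correlation, 9 lists in Treg and 6 in Tcon, and 0 passed with an estimated correlation; heat shock and integrated stress has a median of 0.14 in Treg and 0.33 in Tcon.

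Genes changed in both cell types after SAH were 11: Hspa1a, Hspa1b, Hspa1l, Hsph1, Dnajb1 and the cholesterol exporter gene Abca1 were higher, and Cpt1a, Slc25a20, Slc15a2, Cdk5rap1 and Art2b lower. Of 18 Treg and 103 Tcon calls among the 9784 genes in both tables, 6 were shared upwards and 5 downwards, where independent lists would share 0.116 and 0.00818, and 0 went in opposite directions. Slc15a2 had log2 changes of -0.75 in Treg and -0.70 in Tcon, Cpt1a -0.67 and -0.68, Cdk5rap1 -0.67 and -0.66, and Abca1 0.38 and 0.40. All 11 kept their direction in every left-out fit of both cell types. In Treg 7 of the 11 kept their call without library 01, 02 or 03 and 6 without 04, and in Tcon 6 kept it without 01 and 4 without 03 or 04. The 11 genes lie on 9 chromosomes. Hspa1b (34956436 to 34959238), Hspa1a (34969190 to 34972156) and Hspa1l (34972703 to 34979285) are neighbours on chromosome 17 of mm10, and the first 2 are near-identical copies whose reads the counting could split, so their separate values are uncertain. Cpt1a lies on chromosome 19 (3322334 to 3385733) and Slc15a2 on chromosome 16 (36750177 to 36784962).

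**Figure D3:**
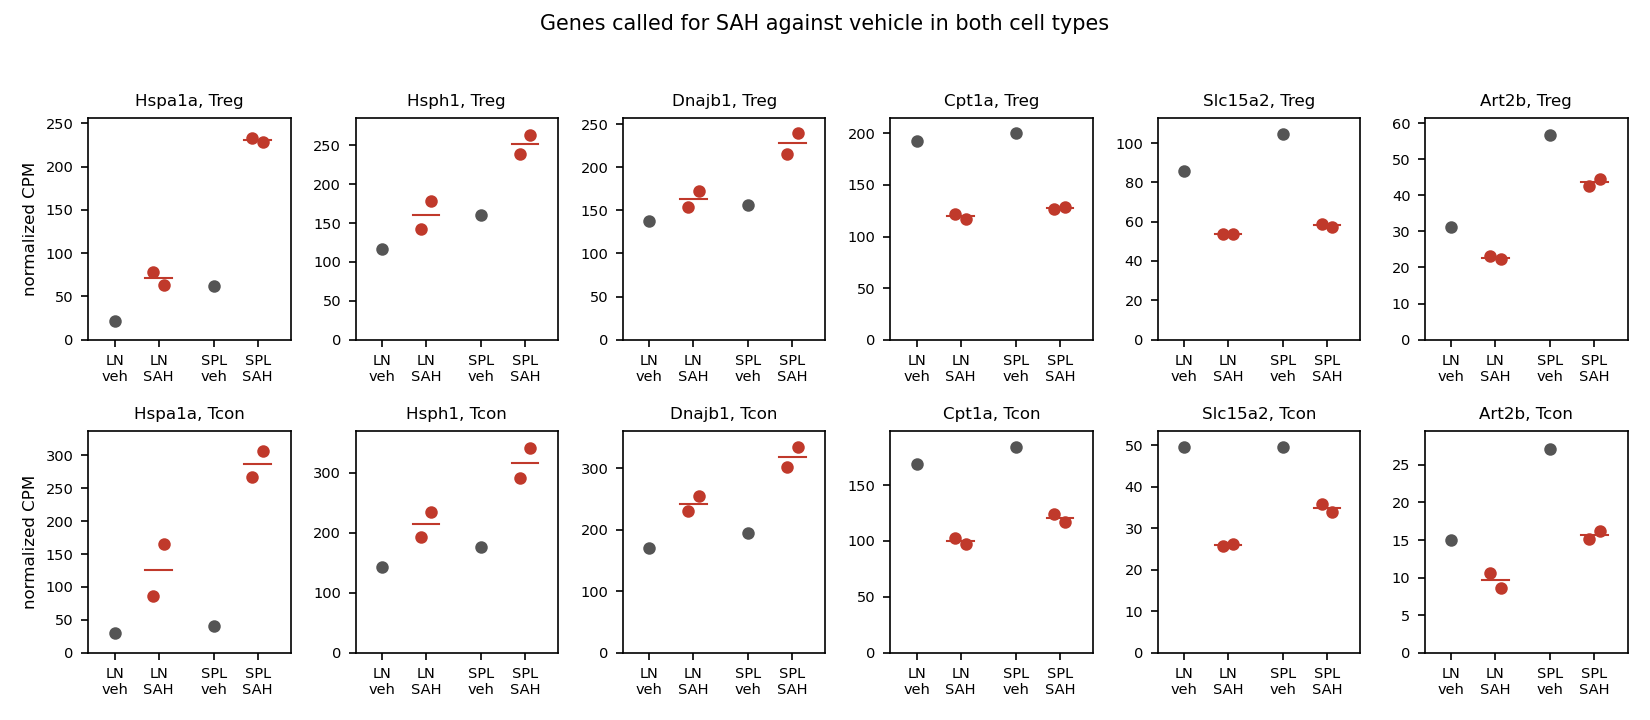
Levels of 6 of the 11 genes called in both cell types (y axis, normalized CPM; upper panels Treg, lower panels Tcon); Hspa1a goes from 62.1 to 231 CPM and Cpt1a from 200 to 128 CPM in spleen Treg. LN is lymph node, SPL spleen and veh vehicle; grey points are single vehicle libraries, red points SAH libraries and red bars means of 2.

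Across the 9784 genes, the SAH effects of Treg and Tcon correlated with Pearson r 0.494 and Spearman rho 0.406; genes are not independent replicates. Differences between SAH libraries of the same treatment correlated between cell types as well, with r 0.438 for lymph node (03 minus 02) and 0.556 for spleen (06 minus 05). The covariance of the SAH effects was 0.00689, and that of the SAH library differences, scaled to the same contrast, was 0.00503 on average.

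The difference of the SAH effect between Treg and Tcon was tested directly. The smallest adjusted p was 0.0615, for Gsg2 (histone kinase haspin), Tob2 and Vegfa. Vegfa was at 6.88 CPM in lymph node vehicle and 15.0 ± 1.07 CPM in SAH in Tcon, and at 3.42 and 3.75 ± 0.849 CPM in Treg (SD, n = 2 each), a log2 difference of effects of -0.96 (95% interval -1.29 to -0.64). Nr4a3 (-0.69) and Nr4a1 (-0.55) were at adjusted p = 0.1. With limma 0 of 9784 genes were called, 453 had an unadjusted p below 0.05, and with the library number as a block, the pairing, 0 were called and 921 had an unadjusted p below 0.05. Other limma settings (pseudocount 0.25, rescaling, 1 symbol for each gene) also gave 0. The count was 7 without Tcon lymph node SAH library 02, and 1 without Treg lymph node SAH library 02 or Treg spleen vehicle library 04.

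In Treg, spleen libraries held more RNA of Jchain, the antibody joining chain made by plasma cells (108 CPM in vehicle and 96.0 ± 33.9 CPM in SAH, against 0.147 and 0.737 ± 0.158 CPM in lymph node; SD, n = 2 each). Lyz2, a lysozyme gene of myeloid cells, was 16.7-fold higher (95% interval 12.6 to 22.1, adjusted p = 5.41e-09), and the red cell genes Slc4a1 and Hbbt1 were 22.9-fold (9.56 to 54.6, adjusted p = 0.000111) and 46.1-fold higher (17.8 to 119, adjusted p = 3.83e-05). Lilrb4, Csf1r, Aqp1 and Ca2 were 8.27-fold, 6.51-fold, 7.61-fold and 6.76-fold higher in spleen, and Gp49a and Lilr4b, which have identical values, 7.15-fold. Without spleen SAH library 06 the log2 differences of Slc4a1, Hbbt1, Aqp1 and Ca2 were 3.37, 4.32, 1.99 and 2.05, and without spleen SAH library 05 those of Slc4a1, Hbbt1 and Aqp1 were 5.41, 6.58 and 3.58. Lymph node Treg held more Itgae (log2 difference -1.53, 95% interval -1.66 to -1.40, adjusted p = 8.72e-10), at 141 CPM in vehicle and 213 and 228 CPM in SAH, against 52.5 and 72.7 ± 6.51 CPM (SD, n = 2) in spleen. Apol9b (-2.17), Apol9a (-2.17), which are near-identical copies, Gcnt1 (-1.88), Wnt10a (-1.66) and Ctsw (-1.63) were also higher in lymph node. Il2ra was 1.35-fold and Nrp1 1.32-fold lower in spleen, Il10 1.6-fold, Ifng 1.4-fold and Cd69 1.23-fold higher, and Foxp3 (log2 difference -0.05, 95% interval -0.16 to 0.07) did not pass.

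Of 10405 genes in Treg, 1531 differed between organs, 906 higher and 625 lower in spleen, with 282 beyond 1.5-fold and 99 beyond 2-fold. Of them 1516 lay on the same side in vehicle and in the SAH libraries, which the call itself favours, as 40.5% of all genes did and 16.7% would by chance. The count was 783 without lymph node vehicle library 01, 768 without lymph node SAH library 02 and 789 without spleen vehicle library 04. Of 22 lists 11 passed, 7 higher and 4 lower in spleen, and none held with an estimated correlation, where the smallest adjusted p was 0.179. Of 10 myeloid and dendritic markers 9 were higher and 1 lower (Ctss at -0.47), 0 not passing (9 and 1 adjusted over the list alone; adjusted p = 2.35e-09, and adjusted p = 0.179 with an estimated correlation). Of 10 B cell markers 8 were higher, 0 lower and 2 not passing (8 adjusted over the list alone; H2-Aa at 2.66, H2-Ab1 at 2.42; adjusted p = 6.64e-07, and adjusted p = 0.336 with an estimated correlation).

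Other lists were higher in spleen Treg as well. Of 25 effector Treg genes 16 were higher, 1 lower and 8 not passing (18 and 3 adjusted over the list alone), with Klrg1 at 2.07 and S100a4 at 0.89 (adjusted p = 6.64e-07, and adjusted p = 0.313 with an estimated correlation). Helper lineage genes (16: 10 higher, 1 lower, 5 not passing; 10 and 1 adjusted over the list alone) included Cxcr3 (0.92) and Ccr6 (-1.09), at adjusted p = 0.000176 and adjusted p = 0.179 with an estimated correlation. Of 30 immediate-early genes 17 were higher, 2 lower and 11 not passing (18 and 3 adjusted over the list alone), with Klf6 at 0.73 and Jun at 0.41 (adjusted p = 4.17e-05, and adjusted p = 0.179 with an estimated correlation). Of 20 cholesterol synthesis genes 13 were higher, 0 lower and 7 not passing (13 adjusted over the list alone), with Idi1 at 0.62 (adjusted p = 6.64e-07, and adjusted p = 0.439 with an estimated correlation). Of 22 heat shock genes 10 were higher, 1 lower and 11 not passing (10 and 2 adjusted over the list alone), with Hspa1b at 1.64 and Atf3 at 1.59 (adjusted p = 0.00134, and adjusted p = 0.179 with an estimated correlation).

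Lower in spleen Treg were 10 of 34 interferon response genes, with 0 higher and 24 not passing (13 lower adjusted over the list alone), such as Ifit3 (-1.19) and Usp18 (-0.56), at adjusted p = 0.000311 and adjusted p = 0.611 with an estimated correlation. Without spleen SAH library 06 the interferon list stood at adjusted p = 0.0804. Of 39 cell cycle genes 10 were lower, 2 higher and 27 not passing (13 lower and 2 higher adjusted over the list alone), with Uhrf1 at -0.60 and Stmn1 at -0.59 (adjusted p = 0.000727, and adjusted p = 0.471 with an estimated correlation). Of 51 ribosomal protein genes 5 were lower, 0 higher and 46 not passing (5 lower adjusted over the list alone), at adjusted p = 8.49e-05 and adjusted p = 0.611 with an estimated correlation. Among them Rps9 (-0.29) was not called without libraries 02 or 03. Of 34 Treg signature genes 12 were lower, 7 higher and 15 not passing (15 lower and 10 higher adjusted over the list alone), with Capg at -0.57, Ikzf4 at -0.59 and Klrg1 at 2.07 (adjusted p = 0.0429, and adjusted p = 0.611 with an estimated correlation). That list stood at adjusted p = 0.0959, adjusted p = 0.0961 and adjusted p = 0.35 without lymph node SAH library 02, lymph node SAH library 03 and spleen SAH library 06.

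In Tcon, Klrb1c (NK1.1) was 10.9-fold higher in spleen (95% interval 8.22 to 14.5, adjusted p = 3.43e-06), with 23.6 and 12.2 ± 1.76 CPM against 0.48 and 0.498 ± 0.235 CPM in lymph node (SD, n = 2 each). Ifng was 6.22-fold higher (5.18 to 7.47, adjusted p = 1.64e-06), and Ccl5, Xcl1, Nkg7 and Zbtb16 were 11.4-fold, 8.38-fold, 7.38-fold and 6.93-fold higher. Jchain stood at 102 and 37.8 ± 1.58 CPM in spleen and 0.373 and 0.295 ± 0.0195 CPM in lymph node (SD, n = 2 each), and Lyz2 was 16.3-fold higher (log2 difference 4.03, 95% interval 3.70 to 4.36). The red cell gene Slc4a1 was listed at 0 in all 3 lymph node libraries and at 4.21 and 26.7 ± 33.0 CPM in spleen (SD, n = 2), a log2 difference of 3.39 called at adjusted p = 0.0227 but not without library 03. Without spleen SAH library 05 or 06 it was 4.26 or 2.24. Apol9b (log2 difference -1.88), Ccr8 (-1.32), Tspan9 (-1.26), Spsb1 (-1.02) and Scd2 (-0.97) were higher in lymph node. Foxp3 (fold 0.905, 95% interval 0.821 to 0.998, adjusted p = 0.277) and Il2ra (1.36, 1.12 to 1.65, adjusted p = 0.0786) did not pass.

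Of 9886 genes in Tcon, 468 differed between organs, 324 higher and 144 lower in spleen, with 162 beyond 1.5-fold and 93 beyond 2-fold. All 468 lay on the same side in vehicle and in the SAH libraries, which the call itself favours, as 30.3% of all genes did and 16.7% would by chance. Left-out fits gave 263 (lymph node vehicle 01), 215 (lymph node SAH 03), 268 (spleen vehicle 04) and 301 (spleen SAH 06). Of 22 lists 17 passed, 16 higher and 1 lower in spleen; with an estimated correlation the smallest adjusted p was 0.111. Of 10 CD8 and natural killer markers 8 were higher, 0 lower and 2 not passing (8 adjusted over the list alone; adjusted p = 2.08e-14, and adjusted p = 0.111 with an estimated correlation), with Cd8b1 at -0.02. Of 8 B cell markers 6 were higher, 0 lower and 2 not passing (8 adjusted over the list alone; H2-Aa at 2.55; adjusted p = 8.36e-13, and adjusted p = 0.111 with an estimated correlation). Of 7 myeloid markers 3 were higher, 0 lower and 4 not passing (3 higher and 1 lower adjusted over the list alone; adjusted p = 4.88e-06, and adjusted p = 0.111 with an estimated correlation).

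Other lists also differed between the organs in Tcon. Of 21 trafficking receptors 10 were higher, 1 lower and 10 not passing (14 and 1 adjusted over the list alone), with Cxcr6 at 2.76, Ccr2 at 2.57 and Cxcr3 at 2.17 (adjusted p = 7.6e-11, and adjusted p = 0.111 with an estimated correlation). Helper lineage genes (15: 9 higher, 0 lower, 6 not passing; 9 higher and 1 lower adjusted over the list alone) included Tbx21 at 2.51 (adjusted p = 7.61e-11, and adjusted p = 0.111 with an estimated correlation). Of 18 effector Treg genes 11 were higher, 1 lower and 6 not passing (13 and 2 adjusted over the list alone; Lgals3 at 1.34; adjusted p = 7.61e-11, and adjusted p = 0.144 with an estimated correlation). Of 20 cholesterol synthesis genes 7 were higher, 0 lower and 13 not passing (16 adjusted over the list alone; adjusted p = 6.42e-11, and adjusted p = 0.157 with an estimated correlation). Of 35 interferon response genes 3 were lower, 0 higher and 32 not passing (19 lower adjusted over the list alone; adjusted p = 1.87e-08, and adjusted p = 0.38 with an estimated correlation). Of these Oas2 (-0.58) was not called without libraries 01, 04 or 06.

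The 9 other lists that passed were higher in spleen Tcon. Of 29 cell cycle genes 2 were higher, 0 lower and 27 not passing (8 adjusted over the list alone; Hmgb2 at 0.39; adjusted p = 1.06e-05, and adjusted p = 0.199 with an estimated correlation). Of 22 heat shock genes 6 were higher, 0 lower and 16 not passing (11 adjusted over the list alone; Atf3 at 1.30; adjusted p = 2.43e-05, and adjusted p = 0.157 with an estimated correlation). Of 28 Treg signature genes 6 were higher, 0 lower and 22 not passing (10 higher and 2 lower adjusted over the list alone; Il2rb at 1.46; adjusted p = 0.000263, and adjusted p = 0.199 with an estimated correlation). Of 10 effector cytokine genes 4 were higher, 1 lower and 5 not passing (5 and 1 adjusted over the list alone; Ifng at 2.64; adjusted p = 0.000329, and adjusted p = 0.111 with an estimated correlation). Of 16 STAT5 and cytokine feedback genes 5 were higher, 2 lower and 9 not passing (7 and 2 adjusted over the list alone; Socs2 at 1.78; adjusted p = 0.00102, and adjusted p = 0.111 with an estimated correlation).

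Lists called in spleen Tcon only with some libraries were 4. Of 29 immediate-early genes 5 were higher, 0 lower and 24 not passing (7 adjusted over the list alone; Nr4a1 at 0.49; adjusted p = 0.000263, and adjusted p = 0.303 with an estimated correlation). Its adjusted p was 0.0656 without lymph node SAH library 02. Of 51 ribosomal protein genes 0 passed (0 adjusted over the list alone) and 45 had a positive difference (adjusted p = 0.0149, and adjusted p = 0.706 with an estimated correlation). The list stood at adjusted p = 0.937 without vehicle library 01 or 04 and adjusted p = 0.273 without lymph node SAH library 03. Of 25 apoptosis and p53 genes 4 were higher, 0 lower and 21 not passing (5 adjusted over the list alone; Bcl2 at 0.33; adjusted p = 0.0227, and adjusted p = 0.295 with an estimated correlation). They stood at adjusted p = 0.112 without vehicle library 01 or 04 and adjusted p = 0.0526 without lymph node SAH library 02. Of 15 FOXP3-repressed genes 2 were higher, 0 lower and 13 not passing (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.025, and adjusted p = 0.176 with an estimated correlation). They stood at adjusted p = 0.0629 without lymph node SAH library 02 and adjusted p = 0.0839 without spleen SAH library 06.

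**Figure D4:**
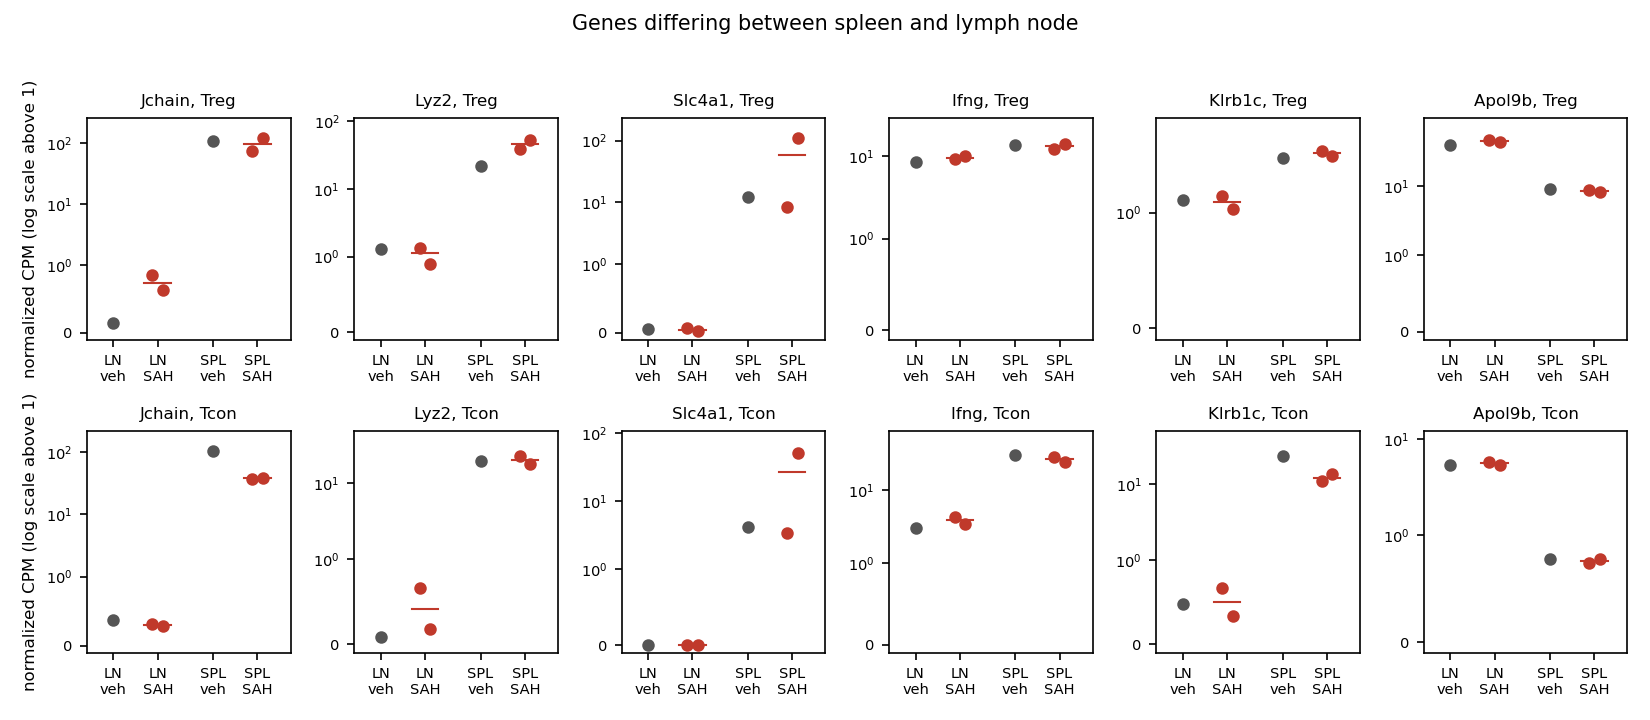
Levels of 6 genes that differed between organs in at least 1 cell type (y axis, normalized CPM, linear from 0 to 1 and logarithmic above; upper panels Treg, lower panels Tcon). LN is lymph node, SPL spleen and veh vehicle, grey points are single vehicle libraries, red points SAH libraries and red bars means of 2; Slc4a1 is highest in spleen SAH library 06, at 110 CPM in Treg and 50.0 CPM in Tcon.

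Whether the SAH effect differed between organs was tested with 1 vehicle library for each organ, which is assumed to vary like the SAH libraries. In Treg, Mrpl33, a mitochondrial ribosomal protein gene, was called. It went from 18.6 to 11.7 ± 0.794 CPM in lymph node and from 12.7 to 21.1 ± 0.520 CPM in spleen (SD, n = 2 each). The log2 difference of effects was 1.32 (95% interval 0.95 to 1.69, adjusted p = 0.0143). In Tcon, Mrpl33 differed more between lymph node SAH libraries, at 25.1 and 16.2 CPM against 15.6 CPM in vehicle. The spleen SAH libraries of Tcon were close, at 17.6 and 17.8 CPM against 18.5 CPM in vehicle. Tmsb10, a thymosin gene, missed the threshold (1.71-fold difference, 95% interval 1.43 to 2.04, adjusted p = 0.0512). In Tcon, Jchain (-1.33, 95% interval -1.74 to -0.92, adjusted p = 0.311) and the immediate-early gene Fos (0.80, 0.51 to 1.10, adjusted p = 0.517) had the smallest p. With limma 1 gene was called in Treg, where 251 had an unadjusted p below 0.05, and 0 in Tcon, where 504 did and where pseudocount 0.25, rescaling and 1 symbol for each gene also gave 0. Mrpl33 was not called without lymph node SAH library 02 (log2 difference 1.38, adjusted p = 0.482) or 03 (1.26, adjusted p = 0.987). In Treg the count was 0 without lymph node SAH library 02 or 03 and 94 or 42 without spleen SAH library 05 or 06, and in Tcon it was 12 without lymph node SAH library 03 and 15 without spleen SAH library 05.

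The authors' deposited table calls 49 genes in Treg (38 up, 11 down) and 317 in Tcon (215 up, 102 down) for SAH against vehicle. All 21 Treg and all 103 Tcon genes called with limma are among them. In the authors' deposited table Hspa1a has a log2 fold change of 1.81 in Treg and 2.45 in Tcon, Cpt1a -0.67 and -0.68, and Jchain, which limma did not call for SAH, -1.37 in Tcon with a false discovery rate of 5.27e-30.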

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

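The list differences between cell types and the tests of handling stress, shared mice, RNA of other cells and shared preparation were chosen after the results they concern were seen. The tests with other libraries as the lone group and the splits of the libraries were chosen before.

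The SAH effect on Mrpl33 in Treg differed between organs by the interaction test of limma (log2 difference 1.32, adjusted p = 0.0143), with the single vehicle libraries assumed to vary like the SAH ones, but not without lymph node SAH library 02 (1.38, adjusted p = 0.482) or 03 (1.26, adjusted p = 0.987). Between Treg and Tcon, the difference of the SAH effect was tested directly with camera of limma at the preset correlation, where 0 genes of any list were called alone. The ribosomal protein list passed with a lower effect in Treg (50 of 51 genes lower, 0 adjusted over the list alone; median log2 difference -0.16, adjusted p = 4.32e-17; adjusted p = 0.45 with an estimated correlation). So did the immediate-early list (22 of 29 lower, 8 lower and 1 higher adjusted over the list alone; -0.26, adjusted p = 4.14e-08; adjusted p = 0.346 with an estimated correlation). The heat shock and integrated stress list passed the same way (18 of 22 lower, 1 adjusted over the list alone; -0.18, adjusted p = 4.97e-08; adjusted p = 0.101 with an estimated correlation). In the STAT5 and cytokine feedback list 12 of 16 were lower (2 adjusted over the list alone; -0.097, adjusted p = 0.0189; adjusted p = 0.395 with an estimated correlation). The effector Treg list passed with a higher effect in Treg (15 of 18 higher, 0 adjusted over the list alone; 0.15, adjusted p = 0.00208; adjusted p = 0.45 with an estimated correlation). In the trafficking receptor list 16 of 21 were higher (1 adjusted over the list alone; 0.062, adjusted p = 0.0189; adjusted p = 0.45 with an estimated correlation). These values take the libraries as independent. No fit with a library left out was run for these list differences, so their dependence on single libraries is not known. In the Tcon fits for SAH, the effector Treg list moved down without lymph node vehicle library 01 and up without spleen vehicle library 04. With the pairing by library number these 6 lists passed as well, and so did 4 more, again with 0 genes called. Interferon response (adjusted p = 5.64e-05; adjusted p = 0.382 with an estimated correlation) and B cell markers (adjusted p = 0.00252; adjusted p = 0.391 with an estimated correlation) had the higher effect in Treg. Cholesterol synthesis (adjusted p = 0.011; adjusted p = 0.382 with an estimated correlation) and glycolysis (adjusted p = 0.0259; adjusted p = 0.391 with an estimated correlation) had the lower.

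Hspa1a, Hspa1b, Hspa1l, Hsph1 and Dnajb1 rose and Cpt1a and Slc25a20 fell with SAH in both cell types. Differences between preparations that have nothing to do with treatment could give such calls: of the 9 choices of 1 lone library per organ, 1 in Treg and 1 in Tcon, the real one, gave as many calls (21, next 11; 103, next 3), and 9 choices are too few for a share under 0.05. Stress from handling the tissue stays open, since the immediate-early list had a median log2 change of 0.0297 in Treg, with members on both sides (5 rose and 0 fell adjusted over the list alone), and 0.26 in Tcon (13 rose and 0 fell). Lymph node and spleen libraries sharing a mouse also stays open, as library differences correlated across organs (r 0.216 in Treg and 0.336 in Tcon across genes, Spearman rho 0.0889 and 0.258), and then the organs would not be independent. Taking 02 with 05 or 03 with 06 as the lone libraries gave 2 and 11 calls in Treg and 1 and 3 in Tcon, and the 6 mixed choices gave 0. In all of these a real SAH effect would enter the spread and keep the count low. With a single pair of SAH libraries per organ the numbers match by chance as easily as not, so whether a mouse was shared stays undecided. An effect of SAH on both cell types is the biological explanation the design names, and with 1 vehicle library per organ it cannot be told apart from these.

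Cells were selected for CD4, with CD25 and FOXP3 for Treg, but whether that removed all other cells was not tested. In spleen, 22 of 30 markers of other cells in Treg and 18 of 28 in Tcon were called higher, and 3 and 0 lower. Among the higher ones Jchain was at 108 and 102 CPM in vehicle and Lyz2 at 21.6 and 19.4 CPM. RNA of other cells may therefore account for part of the genes higher in spleen, and it cannot be told apart from expression by the T cells. Dilution of T cell RNA would lower the genes of all T cells alike, but their list had a median log2 difference of 0.000539 in Treg (SD 0.12) and -0.0292 in Tcon (SD 0.069), against -0.32 and -0.31 for the called lower genes, which argues against it for the genes lower in spleen. Of the 10 splits of 6 libraries into 3 and 3, 1 gave as high a count as the real one for genes (1531 in Treg, highest other 1; 468 in Tcon, highest other 0) and lists (11, highest other 10; 17, highest other 10), and 10 splits are too few for a share under 0.05. Every other split mixes the organs, so a real organ difference would enter its spread and keep its count low. A difference between the T cells of the organs stays open, untested apart from these splits.

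The SAH effects of Treg and Tcon correlated across genes (r 0.494). Libraries of the same number sharing a preparation is a candidate explanation for most of this: differences between SAH libraries of an organ, which hold no treatment, had a mean covariance of 0.00503 between cell types on the scale of the SAH contrast (0.00388 in lymph node, 0.00617 in spleen), against 0.00689 for the SAH effects. The difference of 0.00186 is smaller than the gap between the organs. Each organ gives a single such library difference, whose direction could match between cell types by chance, so a shared preparation is not established. The overlap expected by chance, 0.116 genes up and 0.00818 down, holds for independent libraries and is too low where preparations are shared. A common response to SAH stays open for the 11 shared genes.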

How the results depend on the processing

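The alternatives with limma voom on rebuilt reads, 1 prior variance and 1 symbol for each gene, and the tests of list differences between cell types, were chosen after the results were seen, and the others before. The planned edgeR alternative was not run: the rule for a count test asks for more values within 20 reads than the 16 (Treg) and 27 (Tcon) that a library held at most. The rebuilt reads went to voom. Left-out fits with an arm of 1 library assume that it varies like the other groups. Without vehicle library 01 or 04 the SAH effects equal those of spleen or lymph node alone (log2 change of Hspa1a in Treg 1.88 and 1.67). The organ differences without either equal those of SAH libraries alone. Fits of 1 organ alone set 1 vehicle library against 2 SAH libraries, take their spread from that pair only and assume that vehicle varies like it. No filter removed 0 genes and so tested nothing. The interaction with organ has no value without a vehicle library.

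Genes changed by SAH in Treg were 21. Without an organ term the count was 1, with lymph node alone 121 (19 of the 21 among them), with spleen alone 4, with 1 prior variance 7, and from 7 to 95 with a library left out. Pseudocount 0.25, rescaling, voom and 1 symbol for each gene gave 21, 22, 22 and 22, each with all 21. In Tcon the 103 genes became 1 without an organ term, 41 with lymph node alone, 11 with 1 prior variance, and 11 to 226 with a library left out. Spleen alone gave 126 (56 of the 103 among them) and voom 75. The cause of these changes was not tested.

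Genes differing between organs were 788 in Treg and 262 in Tcon with SAH libraries alone, against 1531 and 468, of which 760 and 239 were shared. With a library left out they ranged from 768 to 1830 and from 215 to 628, and voom gave 1479 and 454. The interaction with organ in Treg gave 2 genes, with Tmsb10 added, at pseudocount 0.25 (adjusted p = 0.0477), with rescaling (adjusted p = 0.0385) and with 1 symbol for each gene (adjusted p = 0.0474), against 1. With a library left out it gave 0 to 94. In Tcon it gave 0 to 15. Between cell types the left-out counts were 0 to 7. The cause was not tested.

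With an estimated correlation 0 lists passed in Treg and 0 in Tcon for SAH, 0 and 0 for organ, and 0 for the difference between cell types, with the pairing or without. That setting rests on few residual degrees of freedom, so these counts do not show that no list moved. Under the replicate block, the pairing by library number, 10 lists differed between cell types instead of 6, all 6 among them, and the block changed no other call. With a library left out, 4 to 11 lists passed for SAH in Treg and 6 to 13 in Tcon. The correlation of SAH effects was 0.572 among 7824 genes with a mean of at least 10 CPM, and 0.357 to 0.498 with a library left out. The cause was not tested.

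Named genes had 171 calls, with a gene counted once in each comparison that called it. Of their 2309 values under the alternatives, no filter included, 2003 kept the call, 306 lost it and 0 reversed. The SAH calls were lost more often, in 84 of 270 values in Treg and 131 of 420 in Tcon. For the organ differences 27 of 805 and 62 of 806 were lost. Among genes that were not called, 37 values changed sign. In Treg with SAH these were, for lymph node alone, Il2ra (0.0031), Tnfrsf18 (0.098), Nrp1 (-0.011), Lyz2 (-0.13) and Lyz1 (-0.082), and for spleen alone Ctla4 (-0.060) and Ifng (-0.050). With a library left out the ranges there were Il2ra -0.080 to 0.010, Ctla4 -0.060 to 0.29, Tnfrsf18 -0.18 to 0.098, Nrp1 -0.011 to 0.081, Ifng -0.050 to 0.14, Lyz2 -0.13 to 1.02 and Lyz1 -0.082 to 0.81. In Tcon with SAH these were Ctla4 (0.0015) and Mki67 (-0.24) for lymph node alone, Ikzf2 (0.11), Tnfrsf18 (-0.10) and Ifng (-0.21) for spleen alone, and Ifng (-0.12) for voom. With a library left out the ranges there were Ctla4 -0.15 to 0.0015, Ikzf2 -0.25 to 0.11, Tnfrsf18 -0.10 to 0.21, Ifng -0.21 to 0.26 and Mki67 -0.24 to 0.32. Between organs in Treg, Mki67 was -0.0071 with SAH libraries alone and -0.020 to 0.11 with a library left out, and Ikzf2 -0.044 to 0.11.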

Other observations

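The tests of HSF1 targets and of fatty acid oxidation genes were chosen after the SAH results were seen.

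Heat shock genes are targets of the transcription factor HSF1, and other targets could be expected to rise with them. Of 23 measured HSF1 targets outside the heat shock list, 20 had a positive change in Treg and 20 in Tcon, with a median log2 change of 0.0542 and 0.0954. The list passed camera of limma at the preset correlation (adjusted p = 0.00032 and adjusted p = 0.000115), but stood at adjusted p = 0.108 and adjusted p = 0.15 with an estimated correlation, so a wider HSF1 response may be present and stays undecided.

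Cpt1a and Slc25a20 act together in fatty acid import, and a lower activity of their shared regulators could lower the other genes of fatty acid oxidation. The mean log2 change of 23 such genes without these was 0.0211 in Treg (SD 0.079) and -0.0102 in Tcon (SD 0.12), against -0.37 and -0.44 for Slc25a20, which argues against a fall of the pathway as a whole.

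Spleen SAH library 06 held the most RNA of the red cell gene Slc4a1 in both cell types, 110 CPM in Treg and 50.0 CPM in Tcon, against 8.41 and 3.38 CPM in library 05 and 12.1 and 4.21 CPM in vehicle library 04. Its source was not tested.

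Jchain was at 102 CPM in spleen Tcon vehicle and at 36.7 and 38.9 CPM in SAH, while spleen Treg had 108 CPM in vehicle and 72.1 and 120 CPM in SAH. It is called lower with SAH in Tcon in the authors' deposited table (false discovery rate 5.27e-30), and not with limma. Lymph node Tcon held at most 0.373 CPM. The B cell gene Cd79a was between 1.33 and 5.08 CPM in all 12 libraries.

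Spleen Tcon held Klrb1c at 23.6, 10.9 and 13.4 CPM and Zbtb16 at 8.98 CPM in vehicle and 7.37 ± 2.2 CPM in SAH (SD, n = 2), genes known from natural killer T cells, against under 1 CPM in lymph node Tcon. Whether naive CD4+ selection admitted such cells in spleen was not tested.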
